A study of Arabidopsis thaliana with 9 samples.

How the data were processed

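The data were RNA-seq libraries from leaves of Arabidopsis thaliana plants 4 to 5 weeks old, from wild-type Col-0, from F1 plants of a cross between Col-0 and ddm1 that carried 1 mutant DDM1 allele, and from homozygous ddm1 plants of the second generation. Each of the 3 groups had 3 libraries, which the labels describe as independent biological replicates. RNA was depleted of ribosomal RNA, made into directional libraries and sequenced as single-end reads of 50 bp, per the labels' protocols. The time of day at harvest, the growth batch and the sequencing batch of each library are not given in the sources used here.

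The deposited values were estimated counts per target made by the authors with kallisto 0.46.0, per the file headers and the submitters' processing notes. The deposited tables also gave TPM, the length-scaled transcript abundances that kallisto computes from the estimated counts and the effective target lengths, per the file headers. The submitters' processing notes also name the genome build TAIR10, STAR and deepTools without versions, R 3.6.1, R 3.5.1 and DESeq2 1.22.2, with no role for any of them. The source of the kallisto index and its fragment length and strand settings are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies, which are common among transposons, may therefore have been shared or assigned to the wrong copy, and values of single transposon copies are uncertain for that reason.

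The tables held 1 target for each of 33602 loci, of which 32835 matched a locus in the RefSeq annotation of TAIR10.1, whose nuclear chromosomes have the same coordinates as TAIR10. The annotation has no biotype called transposable element gene. The TE genes here were the 3881 loci annotated as pseudogenes with an mRNA model and the product "uncharacterized protein", leaving out those whose note begins with "pseudogene of", whether or not a gene or family is named there. All other loci are called non-TE genes, including 279 organelle loci and 4 rRNA loci. Superfamilies were assigned by tblastx (BLAST 2.17.0, E value under 1e-10) to 328 seed loci that the annotation names or that carry a superfamily's reverse transcriptase motif, a method chosen after the data were seen because the annotation names few superfamilies. Of the 294 seeds that could be assigned when left out, 292 received their own superfamily, and 2278 TE genes (58.7%) were assigned. Copia and Gypsy had 128 and 124 seeds, and CACTA, hAT and MULE had 6, 13 and 16. The check with seeds left out therefore says little about the CACTA, hAT and MULE labels. The pericentromere was taken as the 2.5 Mb on either side of the middle of the 1 Mb window with the most TE genes on each chromosome.

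Estimated counts were rounded to whole numbers. Library totals ranged from 15996806 to 22425699 counts, of which 64.7% to 72.8% fell on organelle loci, so that 5209179 to 7570493 nuclear counts per library set the precision. Differential expression was tested with edgeR 4.0.16 in R 4.3.3 using its quasi-likelihood F test with robust dispersions, TMM normalisation and the default filterByExpr filter. All 9 libraries were fitted together, and p-values were adjusted by the Benjamini-Hochberg method over the 18216 tested genes of each contrast, with an adjusted p under 0.05 counted as a call. Adjusted p-values below are from this test unless another is named. Standard errors (SE) of log2 fold changes were computed from the F statistic. CPM values are counts scaled to a library total of 1e6 after TMM normalisation, with all loci in the total. Where a group had 0 counts, the fold was computed against a floor of 3 counts over the whole group and is given as a lower bound. Floors and intervals cover counting error only, since the reads carried no molecular identifiers.

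The share of counts on TE genes and the number of TE genes with a TPM of 1 or more were compared with two-sided exact permutation tests, which cannot give a p below 0.1 for 3 libraries against 3. The F1 position of a TE gene was its F1 level minus the wild-type mean, divided by the ddm1 mean minus the wild-type mean, on normalised CPM, so that 0 is the wild-type level, 1 the ddm1 level and 0.5 the mean of the parents. It was computed for TE genes higher in ddm1 than in wild type with a log2 fold change of 1 or more. F1 libraries were also tested against 3 computed mixes, each the mean of a wild-type and a ddm1 library after scaling. Superfamilies with at least 20 tested TE genes and the location of TE genes were tested with two-sided Fisher exact tests. These count genes as independent units, so their p-values do not measure the spread between plants. Where a cell of an alternative's table was 0, its odds ratio was computed with 0.5 added to each cell. The covariance of fold changes that comes from the shared wild-type libraries was simulated 20 times with unchanged groups, each gene set at its mean over the 9 libraries.

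The naming rule took, per contrast, genes with an adjusted p under 0.05, a mean CPM of at least 3 and no overlap between the libraries of the 2 groups (expected by chance for 10% of genes), ranked by absolute log2 fold change: the 8 most raised and 4 most lowered TE genes and the 8 most raised and 8 most lowered non-TE genes. It added DDM1 and up to 5 members of each gene list with the smallest adjusted p in ddm1 or F1 against wild type. It also added every member of the lists of silenced loci and of ONSEN copies. The 20 lists held silenced loci, ONSEN copies, DNA methylation and repressive histone methylation, DNA demethylases, RNA-directed DNA methylation and small RNAs, histone variants, DNA damage response, salicylic acid defence, jasmonate, photosynthesis, the circadian clock, flowering time, heat shock, cold and drought, flavonoids, aliphatic glucosinolates, senescence, and markers of seed, root and flower. Lists with at least 3 tested members were tested with camera at a correlation of 0.01 and with fry (limma 3.58.1), adjusted over all lists and contrasts. These groups, tests, lists and alternatives were fixed before the data were examined. One entry of the list of silenced loci carried the identifier of another gene and was left out.

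The alternatives were DESeq2 1.42.0, limma-voom, median-ratio scaling (RLE), TMM on nuclear non-TE genes, no filter or a stricter filter on low counts, organelle and rRNA loci left out, only the 2 groups compared, a replicate block, each library left out in turn, nuclear counts as the denominator, TPM limits of 0.5 and 2, TPM in place of CPM, a stricter TE set, and camera with an estimated correlation. The joint omission of F1 library 3 and ddm1 library 3, which lay apart from their groups, was added after the data were seen, as were the alternatives for TE location and superfamily.

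The tests were run on simulated counts drawn for the real genes from the real means and library sizes, with 40 genes changed at each fold. At an 8-fold increase edgeR recovered 70.0% of the changed genes for ddm1 against wild type, 85.0% for F1 against wild type and 82.5% for ddm1 against F1. At a 4-fold increase it recovered 30.0%, 42.5% and 37.5%, and at a 2-fold increase 2.5%, 5.0% and 0%. It called 2, 3 and 5 unchanged genes in these contrasts. With every gene of the F1 set at the parental mean, the recovered F1 position was 0.482, and with every gene set at 0.3 it was 0.279. With the TE genes at 0.5 and the other genes at their real F1 means, it was 0.445.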

Results

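Leaf RNA was measured in 9 libraries, 3 each from wild-type Col-0, from F1 plants with 1 mutant DDM1 allele and from homozygous ddm1 plants of the second generation. DDM1 is a chromatin remodelling ATPase needed for DNA methylation and silencing of transposons, and the series asked how transposon expression in F1 and ddm1 leaves compares with wild type. Estimated counts totalled 19788015, 19054166 and 21542447 in the wild-type libraries, 19437646, 20457703 and 20768385 in F1, and 22425699, 17383909 and 15996806 in ddm1. Organelle loci took 71.6% ± 1.13 (SD, n = 3) of the counts in F1, 67.3% ± 2.33 (n = 3) in wild type and 67.2% ± 0.854 (n = 3) in ddm1, so that the F1 libraries lay above all others (exact permutation p = 0.1 against either group). The chloroplast gene psbA alone took 32.5% to 55.6% of the counts of a library. Within groups, log2 CPM correlated across genes at 0.926 to 0.947 in wild type, 0.910 to 0.952 in F1 and 0.872 to 0.963 in ddm1, where genes are not independent replicates. No 2 libraries of a group agreed within sampling noise (chi-square per gene of 21.9 or more). The DDM1 transcript itself (AT5G66750) was too scarce to check the genotypes, with 3, 12 and 5 counts in wild type, 2, 0 and 8 in F1 and 1, 2 and 2 in ddm1. Without the filter on low counts, its log2 fold change was -1.61 in ddm1 (edgeR, adjusted p = 0.725) and -0.92 in F1 (adjusted p = 0.667) against wild type.

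TE genes took 0.0833% ± 0.0078 (SD, n = 3) of all counts in wild type, 0.959% ± 0.0908 (n = 3) in F1 and 3.02% ± 0.0413 (n = 3) in ddm1. The share was 36.2 times as high in ddm1 and 11.5 times as high in F1 as in wild type, and F1 reached 31.8% of the ddm1 share. The number of TE genes with a TPM of 1 or more was 71 ± 4.58 in wild type, 514 ± 69.3 in F1 and 946 ± 32.7 in ddm1. All libraries of each group lay apart from those of the others in both measures, and each pairwise exact permutation test gave p = 0.1, the smallest this design allows. As a share of nuclear counts only, TE genes took 0.256%, 3.38% and 9.22%.

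**Figure D1:**
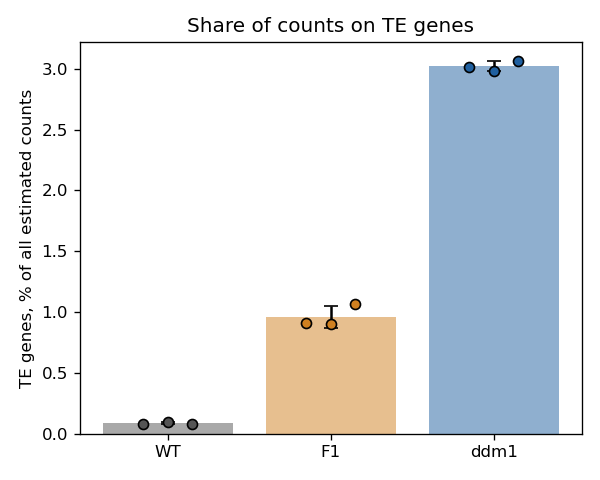
Share of all estimated counts that fell on TE genes, in percent, in the 3 libraries of each group. Bars show group means, error bars the SD and points single libraries. The means rise from 0.0833% in wild type (WT) to 0.959% in F1 and 3.02% in ddm1.

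The first comparison asked which loci differed between ddm1 and wild type. Of 3881 TE genes, 1230 passed the filter on low counts and were tested. Of the tested ones, 1066 (86.7%) were higher and 6 were lower in ddm1 (3 to 6 lower with 1 library left out). The 1066 raised TE genes had a median increase of 134-fold with silent genes counted at their floor, and 856 of them had 0 counts in all wild-type libraries. The most raised TE gene, AT3G32226 on chromosome 3 (13198631 to 13202352, TAIR10), is a CACTA DNA transposon that reached 309 ± 24.9 CPM (SD, n = 3) in ddm1 and had no counts in wild type. It was at least 6740-fold higher (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.28e-06). Of the other CACTA elements, AT1G36200 (262 ± 32.9 CPM), AT1G39110 (244 ± 36.3 CPM) and AT1G35590 (215 ± 33.5 CPM) were raised from 0 counts. The Gypsy retrotransposon AT1G39830 rose from 0 to 230 ± 21.0 CPM (at least 5020-fold). AT4G06720, MEE19 (AT2G34130) and AT5G32306, which had no assigned superfamily, rose from 0 to 291 ± 18.5, 225 ± 22.7 and 214 ± 70 CPM.

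By superfamily, CACTA genes were called higher in ddm1 most often, at 140 of 143 tested (97.9%; Fisher exact odds ratio 8.11, adjusted p = 4.41e-06). Copia retrotransposons (123 of 171, 71.9%; odds ratio 0.316, adjusted p = 1.31e-07) and hAT transposons (13 of 23, 56.5%; odds ratio 0.191, adjusted p = 0.000656) were called higher less often than other TE genes. Gypsy genes (295 of 329, 89.7%; adjusted p = 0.0715) and MULE genes (43 of 55, 78.2%; adjusted p = 0.0715) did not pass the test. Unassigned TE genes were called at 437 of 486 (adjusted p = 0.0115). These rates cover loci that passed the filter on low counts, which a locus silent in wild type passed only through its F1 or ddm1 counts. The tested share of all loci was 61.1% for CACTA, 35.4% for hAT and 33.2% for Copia. It was 30.3% for unassigned, 29.2% for Gypsy and 23.3% for MULE genes. In the pericentromeres 882 of 978 tested TE genes (90.2%) were higher in ddm1, against 184 of 252 (73.0%) on the arms (odds ratio 3.39, Fisher exact p = 3.16e-11). TE genes measured in the same libraries, some of which may share reads, are not independent units in these Fisher tests. The Copia difference did not pass the test without a filter on low counts (odds ratio 0.848, Fisher exact p = 0.191), and under that setting Gypsy genes were called less often than other TE genes (odds ratio 0.754, Fisher exact p = 0.00168). Without organelle and rRNA loci they were called more often (odds ratio 1.57, Fisher exact p = 0.0306), so the direction for Gypsy depended on the processing. With 1 library left out, the odds ratios were nearer 1, at 2.11 to 2.45 for the pericentromeres, 3.27 to 5.18 for CACTA and 0.403 to 0.572 for Copia, and each still passed the test. The filter on low counts was rerun in those fits with a smaller smallest group, so the tested TE genes could differ as well. The pericentromere odds ratio was 1.42 (Fisher exact p = 0.00078) without a filter on low counts.

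The 6 TE genes lowered in ddm1 had a median decrease of 32.4-fold with silent genes at their floor. Of these, 4 had at most 3 counts over the ddm1 libraries. Those that the naming rule took were AT1G58561 and AT4G08110. AT1G58561, a Copia element on chromosome 1 (21748675 to 21753246), fell by 2.09 on the log2 scale (SE 0.34, adjusted p = 0.00328), from 57.8 ± 3.42 to 13.5 ± 6.58 CPM. It lies on the same strand within the span of AT1G58602 (21746354 to 21766048), which encodes an NB-ARC disease resistance protein known as RPP7. AT1G58602 was the most lowered non-TE gene with a mean of at least 3 CPM over all libraries, with a log2 fold change of -6.44 (SE 0.88, adjusted p = 0.000994) and levels of 145 ± 1.41 CPM in wild type and 1.60 ± 2.07 CPM in ddm1. AT4G08110 fell by 0.90 (SE 0.18, adjusted p = 0.0121), a call that was lost without wild-type library 3 (adjusted p = 0.0576) or ddm1 library 2 (adjusted p = 0.0688).

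Among 16986 tested non-TE genes, 185 were higher and 85 lower in ddm1. The raised genes had a median increase of 33.5-fold with silent genes at their floor, and 99 had 0 counts in wild type. The most raised by the naming rule was the noncoding RNA AT2G15555 (70.9 ± 27.4 CPM in ddm1, at least 1550-fold), followed by the zinc finger gene AT3G45525, which also rose from 0 counts but whose mean of 67.2 CPM had an SD of 89.7. Next came AT1G44040, AT1G41890 and AT5G33251, which rose from 0 to 37.0, 31.5 and 30.3 CPM. The Ulp1 protease family gene AT5G28810 (29.1 ± 2.75 CPM, at least 636-fold), the myosin heavy chain-like gene AT5G38190 (22.1 ± 6.04 CPM, at least 483-fold) and AT4G06622 (20.1 CPM) followed. AT5G33251 and AT4G06622 are annotated as pseudogenes of an unknown protein. Of the lowered genes, JAZ7 (AT2G34600), a jasmonate signalling repressor, changed by a log2 fold change of -4.26 (SE 0.91, adjusted p = 0.0166), with 32.1 ± 30.9 CPM in wild type and 1.67 ± 0.78 in ddm1. The methyl esterase MES16 (AT4G16690) fell by 3.19 on that scale (SE 0.57, adjusted p = 0.00595). The tetratricopeptide gene AT1G04770 (log2 fold change -3.56, SE 0.52, adjusted p = 0.00167) and the phosphatidylinositol kinase-like gene AT5G24240 (-3.03, SE 0.33, adjusted p = 0.000198) were lower too. The thaumatin-like gene AT4G36010, the ChaC-like gene AT5G26220 and the CBS domain gene AT5G53750 were lower as well, and these 3 calls were each lost when at least 1 library was left out. Among 33 named genes called in this contrast, 22 kept their call whichever library was left out. The JAZ7 call was lost without ddm1 library 1 (adjusted p = 0.0750) or 2 (adjusted p = 0.0848). Raised non-TE genes numbered 123 without ddm1 library 2 and 338 without ddm1 library 3. Lowered ones numbered 42 without wild-type library 1 and 35, 41 and 190 without ddm1 libraries 1, 2 and 3. DESeq2 called 286 raised and 226 lowered non-TE genes, and it also called 45 unchanged genes in the simulation where edgeR called 2.

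Of the loci listed as silenced by DNA methylation, 8 of 14 could be tested in ddm1 and 1 was higher (2 higher when adjusted over the list alone). Not all of them were silent in the wild-type leaves. SDC, an F-box gene, reached 6.65 ± 7.13 CPM in ddm1 against 0.0773 ± 0.134 in wild type (log2 fold change 6.32, SE 1.27, adjusted p = 0.0120), with 35, 65 and 219 counts in the ddm1 libraries. It was not called without wild-type library 1 (adjusted p = 0.0548) or 3 (adjusted p = 0.0515). AtMu1, a MULE transposon, had 33, 50 and 14 counts in ddm1 and 0 in wild type (adjusted p = 0.0560). FWA, a homeobox gene, was too scarce to test and had 29, 2 and 19 counts in ddm1 and 0 in the other 6 libraries. The Copia element EVD had 6, 1 and 0 counts in ddm1 and 0 elsewhere. HDG3, HDG8 and HDG9 had 0 counts in every library, and MPC had 4 counts in 1 wild-type library. QQS, SNC1, RPP4, RPP5, PAI1 and PAI2 were not called, with log2 fold changes of 0.43, 0.12, -0.05, 0.14, -1.09 and 0.44. In wild type they stood at 3.82, 194, 43.2, 128, 2.51 and 1.47 CPM. These genes were thus expressed there, and their values do not tell whether silent loci stayed silent in ddm1. Of 8 copies of the heat-responsive Copia family ONSEN, 1 (AT1G21945) could be tested and did not differ in any contrast (log2 fold change 0.06 in ddm1, adjusted p = 0.981). The others had at most 11 counts in a library. AT1G21945 stood at 150 ± 41.8 CPM in wild type, 111 ± 50.2 in F1 and 156 ± 42.4 in ddm1. It was thus not silent in wild type and does not tell whether silent copies respond to ddm1. Which transcript its reads came from was not checked.

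Few genes of the other lists were called in ddm1. The jasmonate list had 2 lower members of 16 tested, JAZ7 and JAZ10 (1 higher and 5 lower when adjusted over the list alone; camera adjusted p = 0.00121, and adjusted p = 0.626 with an estimated correlation). Wild-type library 1 stood apart in this list and raised its wild-type means. It had 139, 220, 27.1 and 67.9 CPM of OPR3, JAZ1, JAZ5 and JAZ7, against 30.1, 42.6, 3.85 and 15.1 in library 2 and 38.9, 83.1, 4.62 and 13.5 in library 3. No member of the 13 aliphatic glucosinolate genes was called (0 when adjusted over the list alone), although their median log2 fold change was -1.12 (camera adjusted p = 3.36e-07, and adjusted p = 0.617 with an estimated correlation). Among ddm1 libraries, library 3 was near wild type for several members, with CYP83A1 at 64.8, 92.2 and 188 CPM (156 to 239 in wild type) and MAM1 at 15.8, 52.0 and 118 CPM (67.5 to 175 in wild type). Camera also called the flavonoid list (1 of 10 lower, FLS1, and 1 when adjusted over the list alone; adjusted p = 0.0362, and adjusted p = 0.668 with an estimated correlation). Wild-type library 3 and ddm1 library 1 stood apart in the late flavonoid genes, with LDOX at 0.30, 0.74 and 6.04 CPM in wild type and 4.36, 0.06 and 0 in ddm1, and UF3GT at 1.1, 0.42 and 7.89 and at 5.12, 0 and 0. Camera called the cold and drought list as well (0 of 11 members called, and 0 when adjusted over the list alone; adjusted p = 0.0459, and adjusted p = 0.668 with an estimated correlation). The heat shock genes HSP101 and HSFA2 were higher, 2 of 4 tested (2 when adjusted over the list alone). These calls rested largely on ddm1 library 1, with 216, 19 and 11 HSFA2 counts and 194, 52 and 36 HSP101 counts in ddm1 libraries 1, 2 and 3. They were lost when any of 7 libraries (HSP101) or any of 6 (HSFA2) was left out, and without ddm1 library 1 the adjusted p was 0.237 and 0.32. FLC, a repressor of flowering, was the 1 lower gene of 11 in the flowering time list, and CCA1 (log2 fold change -0.83, SE 0.18, adjusted p = 0.0188) the 1 lower gene of 15 in the clock list, both also when adjusted over the list alone. The CCA1 and JAZ10 calls were each lost when any of 4 libraries was left out, and the FLS1 call when any of 7 was. Fry called none of the 4 lists that camera called here (adjusted p = 0.244 for jasmonate, 0.135 for glucosinolate, 0.347 for flavonoid and 0.409 for cold and drought genes). The DNA damage list had 0 of 9 called (1 higher when adjusted over the list alone). No member was called, over all genes or when adjusted over the list alone, among 11 DNA and histone methylation genes, 4 demethylase genes, 25 small RNA genes, 20 histone variants, 22 salicylic acid defence genes, 24 photosynthesis genes and 6 senescence genes. No seed marker of 9 could be tested in any contrast. The root marker SCR and the flower markers SEP1 and VGD1 were not called in any contrast. VGD1 had 17, 164 and 0 counts in wild type, 1, 4 and 2 in F1 and 9, 13 and 4 in ddm1, and it was lower in F1 when adjusted over the list alone.

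The second comparison set F1 against wild type. Of 1230 tested TE genes, 866 (70.4%) were higher and 4 lower in F1 (2 to 9 lower with 1 library left out). The raised ones had a median increase of 49.1-fold with silent genes at their floor, 669 of them from 0 counts. With only the F1 and wild-type libraries filtered and fitted, 587 TE genes were called in either direction. The CACTA gene AT1G39110 reached 119 ± 5.17 CPM in F1 (at least 2590-fold, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 2.70e-06) from 0 in wild type. MEE19 reached 121 ± 18.4 CPM (at least 2650-fold) and the Gypsy gene AT1G39830 reached 86.7 ± 7.15 CPM (at least 1890-fold), also from 0. The CACTA genes AT1G36460 and AT3G30396 reached 73.0 ± 2.86 and 63.3 ± 11.7 CPM, and the unassigned AT2G13160 and AT1G36190 reached 112 ± 38.3 and 64.1 ± 7.89 CPM. The Gypsy gene AT4G04170 averaged 123 CPM with an SD of 118. The Copia gene AT5G35777 was lower in F1 (log2 fold change -2.01, SE 0.47, adjusted p = 0.0149), a call that was lost without wild-type library 1. AtMu1 was called higher in F1 (adjusted p = 0.0359) on 37, 0 and 24 counts, and lost its call without any one of 7 libraries.

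Of the 866 TE genes higher in F1, 848 (97.9%) were also higher in ddm1. Independent lists of these sizes would share 751. The fold changes of TE genes in the 2 contrasts had a covariance of 5.47 (0.213 simulated) and a correlation of 0.788 across genes (0.490 simulated). The simulation set wild type at the mean of all 9 libraries, whereas 669 of the 866 genes had 0 counts there. The simulated values therefore do not measure the noise that the shared controls give to those genes. Splitting the 3 control libraries would leave fewer than 2 in a part, so they were not split, and part of the excess may come from the shared controls. With only the 2 groups of each contrast fitted, 565 TE genes were higher in both. CACTA genes were called higher in F1 at 135 of 143 (odds ratio 8.21, Fisher exact adjusted p = 5.33e-13) and Gypsy genes less often, at 209 of 329 (odds ratio 0.647, adjusted p = 0.00561). The rates were 116 of 171 for Copia (adjusted p = 0.502), 13 of 23 for hAT (adjusted p = 0.332), 35 of 55 for MULE (adjusted p = 0.435) and 345 of 486 for unassigned genes (adjusted p = 0.75). Pericentromeric TE genes were called at 71.9% and those on the arms at 64.7% (odds ratio 1.40, Fisher exact p = 0.0301), a difference that did not pass the test under 8 other settings, with p from 0.0505 to 0.169.

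Non-TE genes differed widely between F1 and wild type. Of 16986 tested, 1600 were higher, with a median increase of 2.43-fold, and 1756 were lower, with a median decrease of 3.72-fold. The most lowered genes by the naming rule included CSLA01 (AT4G16590), a cellulose synthase-like gene, and the carboxypeptidase-like gene scpl10 (AT2G23000), which had 0 counts in F1 and 20.9 ± 17.8 and 9.53 ± 3.14 CPM in wild type, at least 392-fold and 179-fold lower. AT5G15948 also had 0 counts in F1 and 4.94 ± 5.00 CPM in wild type. LpxC1 (AT1G24793), AT1G13650, the phosphate translocator gene PPT2 (AT3G01550) and the helix-loop-helix gene AT5G50915 had 1, 1, 5 and 4 counts in F1 against 10.2, 21.2, 19.3 and 8.79 CPM in wild type. The AT5G50915 call was lost when any of 5 libraries was left out. Genes raised from 0 counts were the noncoding RNA AT2G15555 (57.7 ± 6.43 CPM) and 3 Ulp1 protease family genes, AT5G28810 (18.7 ± 2.18 CPM), AT4G08430 (10.5 ± 2.30 CPM) and AT5G28235 (7.66 ± 1.28 CPM). The nucleic acid-binding gene AT2G05642 (4.09 ± 2.57 CPM), AT1G44040, AT5G33251 and FKF1 were raised from 0 as well. Higher calls were shared with ddm1 for 138 non-TE genes (17 for independent lists) and lower calls for 50 (8.8 for independent lists). The fold changes had a covariance of 0.377 (0.132 simulated) and a correlation of 0.423 across genes (0.495 simulated). Raised non-TE genes numbered 867, 572 and 1028 without wild-type libraries 1, 2 and 3, 685 and 727 without F1 libraries 1 and 2, and 1033 and 964 without ddm1 libraries 1 and 2. Lowered ones numbered 1145 and 1163 without wild-type libraries 1 and 2 and 874 and 964 without F1 libraries 1 and 2. Among 73 named genes called in this contrast, 52 kept their call whichever library was left out.

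Most clock genes differed between F1 and wild type, while PRR7 and PRR9 overlapped between the groups. LHY (AT1G01060), a morning-expressed transcription factor of the clock, had 91.7 ± 5.94 CPM in wild type and 0.913 ± 0.358 in F1 (log2 fold change -6.64, SE 0.33, adjusted p = 2.54e-06). Its partner CCA1 had 54.9 ± 8.44 and 3.65 ± 0.313 CPM (log2 fold change -3.91, SE 0.21, adjusted p = 2.77e-06). The evening gene TOC1 rose from 4.94 ± 0.839 to 97.3 ± 13.6 CPM (log2 fold change 4.30, SE 0.25, adjusted p = 4.07e-06). COR27 rose from 0.214 ± 0.0644 to 17.7 ± 5.12 CPM, and FKF1, a blue-light receptor gene, rose from 0 counts to 15 ± 3.68 CPM, at least 328-fold. Of 15 clock genes, 10 were higher and 3 lower in F1 (the same numbers when adjusted over the list alone; camera adjusted p = 0.0133, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.00568). RVE8 was the other lower gene, and COR28 and BOA were also higher. In ddm1, LHY stood at 63.5 ± 9.51 CPM, CCA1 at 30.8 ± 1.49 and TOC1 at 4.2 ± 0.657, and FKF1 again had 0 counts.

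**Figure D2:**
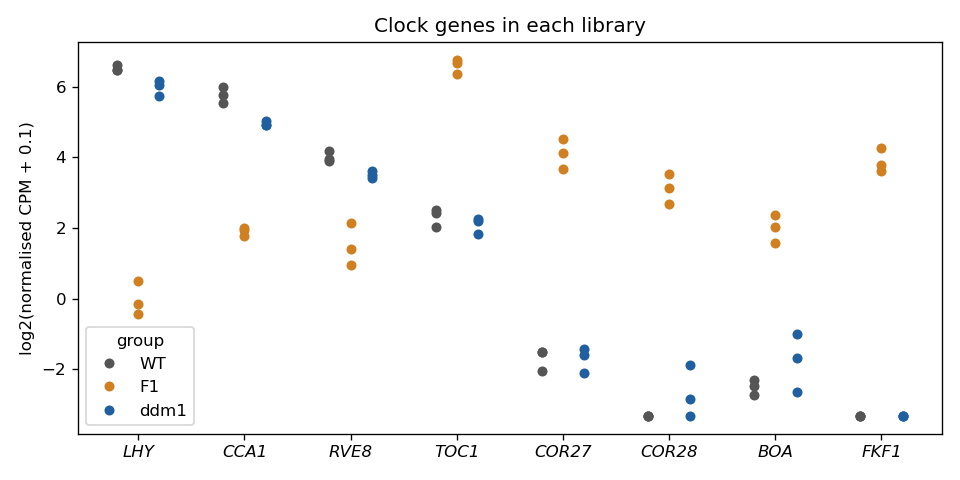
Normalised expression, as log2 of CPM plus 0.1, of 8 clock genes in each of the 9 libraries, with 1 point per library and groups set apart by colour. LHY, CCA1 and RVE8 are low and TOC1, COR27, COR28, BOA and FKF1 high in the F1 libraries. FKF1 has 0 counts in wild type (WT) and ddm1.

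Photosynthesis genes were lower in F1, 19 of 24 (20 when adjusted over the list alone; median log2 fold change -2.24, camera adjusted p = 1.95e-13, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.0245). The light-harvesting genes LHCB1.1 and LHCB2.1 stood at 1270 ± 625 and 1400 ± 399 CPM in wild type and at 24.2 ± 5.84 and 37.8 ± 15.2 in F1. RCA, which encodes Rubisco activase, fell by 2.43 (SE 0.25, adjusted p = 0.000154). Aliphatic glucosinolate genes were lower in 10 of 13 cases (12 when adjusted over the list alone; camera adjusted p = 1.96e-07, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.0334). The regulator MYB29 led them (log2 fold change -6.16, SE 0.86, adjusted p = 0.00108). In the flavonoid list 5 of 10 were lower (7 when adjusted over the list alone; camera adjusted p = 0.00110, and adjusted p = 0.617 with an estimated correlation). Among them were CHS, the entry enzyme of the pathway (-5.54, SE 0.60, adjusted p = 0.000232), and the anthocyanin regulator PAP1 (-7.30, SE 1.02, adjusted p = 0.00110). The FLS1 and F3'H calls in this list were lost without wild-type library 2 (adjusted p = 0.108 and 0.0628). They were also lost without certain other single libraries, such as F1 library 1 (adjusted p = 0.107 and 0.131). In the jasmonate list 4 of 16 genes, LOX2, AOS, JAZ7 and VSP2, were lower and PDF1.2 was higher (5 lower and 1 higher when adjusted over the list alone; camera adjusted p = 0.00488, and adjusted p = 0.668 with an estimated correlation). Histone variants were higher in 7 of 20 cases (8 when adjusted over the list alone; camera adjusted p = 0.0267, and adjusted p = 0.626 with an estimated correlation; fry adjusted p = 0.0385). Without wild-type library 1, the calls of the histone variants HTA9, HTA1 and HTR8 were lost (edgeR adjusted p = 0.0606, 0.0675 and 0.0919). Each was also lost when certain other single libraries were left out, such as wild-type library 3 (edgeR adjusted p = 0.0608, 0.0695 and 0.0844). Fry did not call the flavonoid (adjusted p = 0.0523) and jasmonate (adjusted p = 0.193) lists. The linker histone gene H1.1 rose from 9.46 ± 1.13 to 36.4 ± 8.43 CPM (log2 fold change 1.94, SE 0.22, adjusted p = 0.000302).

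Of 22 salicylic acid defence genes, 3 were higher in F1 (3 when adjusted over the list alone; camera adjusted p = 0.0632). PR1, a marker of that pathway, led them with 9.05 ± 5.04 CPM in F1 and 0.0654 ± 0.0767 in wild type (log2 fold change 7.05, SE 0.97, adjusted p = 0.00102). PR5 and ICS1 were the others. The senescence genes SEN1, at 425 ± 270 CPM in F1 and 21.3 ± 13.8 in wild type, and WRKY6 were higher, 2 of 6 tested (2 when adjusted over the list alone; camera adjusted p = 0.149). CMT3, a DNA methyltransferase gene, was the 1 lower gene of 11 in its list (log2 fold change -2.59, SE 0.69, adjusted p = 0.0259), also when adjusted over the list alone. The same held for DML3, the 1 lower gene of 4 demethylases, and PARP1, the 1 lower gene of 9 in the DNA damage list. AGO3 was higher and AGO10 lower among 25 small RNA genes (0 higher and 1 lower when adjusted over the list alone). FLC was the 1 lower gene of 11 in the flowering list, also when adjusted over the list alone, and P5CS1 the 1 lower gene of 11 in the cold and drought list (0 when adjusted over the list alone). No heat shock gene of 4 was called, and of the silenced loci AtMu1 alone was called, of 8 (0 for both when adjusted over the list alone). The calls of CMT3, DML3, AGO3, P5CS1, JAZ7, LOX2, VSP2, PDF1.2, PR5 and ICS1 were each lost when at least 1 library was left out. So were those of the photosynthesis genes RBCS1B and LHCB1.2 and the glucosinolate gene SOT17.

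The third comparison set ddm1 against F1. Of 1230 tested TE genes, 546 (44.4%) were higher and 8 lower in ddm1 (5 to 9 lower with 1 library left out). The raised ones had a median fold of 10 with silent genes at their floor. AT1G35650 had 29.0 ± 15.9 CPM in ddm1, 0 counts in F1 and 4 counts in wild type (at least 544-fold higher in ddm1 than in F1, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.00286). The Gypsy genes AT1G35647 and AT2G10180 stood at 87.0 ± 48.8 and 15.3 ± 11.4 CPM in ddm1 and at 0.262 ± 0.454 and 0.185 ± 0.320 in F1. The CACTA genes AT1G40123 and AT3G42653 reached 35.0 ± 15.6 and 12.1 ± 3.96 CPM. The unassigned AT5G13475, AT3G33127 and AT1G36520 reached 31.7 ± 9.58, 21.3 ± 5.92 and 17.5 ± 6.02 CPM, and all 5 were under 0.5 CPM in F1. Lower in ddm1 than in F1 were AT4G04170 (log2 fold change -2.80, SE 0.68, adjusted p = 0.0329), AT3G42806 (-1.93, SE 0.36, adjusted p = 0.0101), AT1G58561 (-1.87, SE 0.34, adjusted p = 0.00902) and SADHU7-1 (-1.53, SE 0.37, adjusted p = 0.0255). AT4G04170 and SADHU7-1 lost their calls when at least 1 library was left out. Gypsy genes were called higher in ddm1 than in F1 more often than other TE genes (181 of 329, 55.0%; odds ratio 1.80, Fisher exact adjusted p = 1.46e-05). Copia (36 of 171; odds ratio 0.287, adjusted p = 5.64e-11), MULE (8 of 55; odds ratio 0.202, adjusted p = 7.11e-06) and hAT genes (1 of 23; odds ratio 0.0553, adjusted p = 3.90e-05) were called less often, and CACTA genes at 71 of 143 (adjusted p = 0.181). Unassigned TE genes were called more often than the others (243 of 486, odds ratio 1.45, Fisher exact adjusted p = 0.00182). In pericentromeres 49.5% and on arms 24.6% of tested TE genes were higher (odds ratio 3, Fisher exact p = 6.45e-13). TE genes called higher numbered 252 and 310 without F1 libraries 1 and 2 and 332 and 329 without ddm1 libraries 1 and 2.

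Among non-TE genes 1330 were higher and 1123 lower in ddm1 than in F1. The MADS-box gene AT1G59930 stood at 347 ± 178 CPM in ddm1 and 3.02 ± 0.824 in F1 (log2 fold change 6.84, SE 0.50, adjusted p = 0.000398) and the MADS-box gene AT1G59920 at 20.4 ± 11.4 and 0.123 ± 0.115 CPM. CSLA01, scpl10 and AT5G15948, at 0 counts in F1, stood at 7.66 ± 5.64, 3.58 ± 2.95 and 8.99 ± 6.43 CPM in ddm1, and LpxC1, PPT2 and the hydrolase gene NUDT24 were also higher. Lower in ddm1 were FKF1 and AT1G17665, both at 0 counts in ddm1 and at 15 ± 3.68 and 13.8 ± 3.63 CPM in F1 (at least 282-fold and 257-fold lower). The others were COR27, SEN1 (5.86 ± 4.16 against 425 ± 270 CPM), the glyoxalase genes GLYI4 and GLYI7, the lipase gene MPL1 and AT4G15610. Photosynthesis genes were higher in ddm1, 17 of 24 (22 when adjusted over the list alone; camera adjusted p = 1.24e-12, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.0154). Within ddm1, library 3 stood apart in the photosynthesis list, with LHCB1.1 at 462, 585 and 2303 CPM and RBCS1A at 892, 816 and 3178 CPM. In the clock list 3 genes were higher and 10 lower of 15 (the same numbers when adjusted over the list alone; camera adjusted p = 0.00110, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.00568). Lower lists were histone variants (6 of 20, and 9 when adjusted over the list alone; camera adjusted p = 0.00219, and adjusted p = 0.617 with an estimated correlation; fry adjusted p = 0.0168) and salicylic acid defence (3 of 22, PR1, PBS3 and ALD1, and 3 when adjusted over the list alone; camera adjusted p = 0.00184, and adjusted p = 0.626 with an estimated correlation). Senescence genes were lower in 3 of 6 cases (3 when adjusted over the list alone; camera adjusted p = 0.00488, and adjusted p = 0.626 with an estimated correlation). Glucosinolate genes were higher in 2 of 13 cases (2 when adjusted over the list alone; camera adjusted p = 0.0196, and adjusted p = 0.668 with an estimated correlation) and flavonoid genes in 3 of 10 (3 when adjusted over the list alone; camera adjusted p = 0.0502). In the jasmonate list LOX2 was higher and JAZ10 lower (1 and 1 when adjusted over the list alone). SDC was higher among silenced loci (1 when adjusted over the list alone), and CMT3 and AGO4 were higher in their lists (0 when adjusted over each list alone). None was called among demethylases, DNA damage, flowering time, heat shock, and cold and drought genes, and when adjusted over the list alone 1 heat shock gene was higher. Fry did not call salicylic acid defence (adjusted p = 0.182), senescence (adjusted p = 0.0966) or glucosinolate genes (adjusted p = 0.228). Among 61 named genes called in this contrast, 40 kept their call whichever library was left out. Of the genes named above, AT2G10180, CSLA01, LpxC1, NUDT24, GLYI7, MPL1, SDC, CMT3, AGO4, PBS3, ALD1, LOX2 and JAZ10 each lost their call when at least 1 library was left out, CSLA01 and JAZ10 in 6 of the 9 cases. Without F1 library 1, the histone variants HTA7, HTA9 and HTA1 lost their calls (adjusted p = 0.134, 0.0783 and 0.0856). HTA7 lost its call whichever library was left out, and HTA9 and HTA1 also lost theirs without F1 library 2 (adjusted p = 0.0856 and 0.072). The glucosinolate gene CYP83A1 (adjusted p = 0.126), LHCB1.2 and the senescence gene ORE1 were also not called without F1 library 1. Each of them lost its call without certain other single libraries too. Higher non-TE genes numbered 428 and 525 without F1 libraries 1 and 2, and 2161 with DESeq2. Lower ones numbered 728 without wild-type library 3, 254 and 296 without F1 libraries 1 and 2, 301, 346 and 667 without ddm1 libraries 1, 2 and 3, and 694 without a filter on low counts.

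The level of TE genes in F1 was then placed between its parents. Over 1065 TE genes higher in ddm1 than in wild type, the median F1 position was 0.236, 0.264 and 0.286 in the 3 F1 libraries, with a mean of 0.262 ± 0.025 (SD, n = 3), where 0.5 is the mean of the parents. Single genes spread widely, with quartiles at 0.084 and 0.515. The position was below 0.25 for 44.3% of the genes, above 0.75 for 8.1% and below 0.5 for 73.1%. Summed over the set, TE genes had 77.2 CPM in wild type, 9559 in F1 and 29290 in ddm1, a position of 0.325. The CACTA gene AT1G39110 lay at 0.487 and AT1G39830 at 0.377, while AT3G32226 lay at 0.189, AT4G06720 at 0.031, AT1G35650 at -0.002 and AT4G04170, higher in F1 than in ddm1, at 6.98. By superfamily the median position was 0.203 for Gypsy, 0.247 for unassigned genes, 0.376 for MULE, 0.393 for CACTA, 0.404 for Copia and 0.520 for hAT, and it was 0.271 in pericentromeres and 0.380 on the arms. These differences between superfamilies and locations were not tested. Without F1 library 3 the mean position was 0.223, and on deposited TPM it was 0.236.

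**Figure D3:**
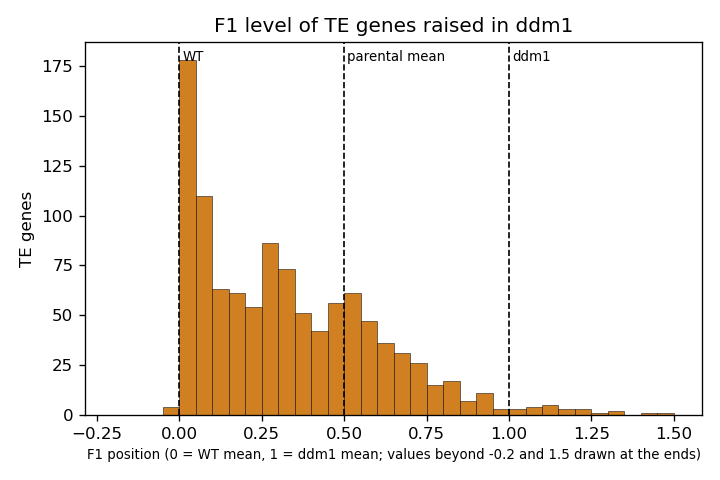
Number of TE genes, out of 1065 raised in ddm1, by their F1 position, where 0 is the wild-type mean (WT), 0.5 the parental mean and 1 the ddm1 mean. Positions beyond -0.2 and 1.5 are drawn at the ends. The position lies below 0.5 for 73.1% of the genes.

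Tested against computed mixes of the parents, 311 of 974 TE genes were below the parental mean and 16 above it (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes). Adjusted over the TE set alone these numbers were 332 and 19. Of 16417 non-TE genes, the test over all genes called 2298 below and 1965 above the parental mean. For the TE set, the median log2 ratio of F1 to the mixes was -0.77. In simulated data with every TE gene at the parental mean and the other genes at their real F1 levels, the same test called 16 below and 15 above, and 0 and 0 when adjusted over the set alone. With every TE gene at a position of 0.3, it called 142 and 3, or 35 and 1 over the set alone. The real count below the mean was 202, 154 and 184 without wild-type libraries 1, 2 and 3, 205 without F1 library 1 and 204, 152 and 178 without ddm1 libraries 1, 2 and 3. The count above it was 4, 2 and 3 without wild-type libraries 1, 2 and 3, 3, 5 and 29 without F1 libraries 1, 2 and 3, and 4, 3 and 3 without ddm1 libraries 1, 2 and 3.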

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

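The joint omission of F1 library 3 and ddm1 library 3 and the settings for TE location and superfamily were chosen after the results were seen, and the other settings before. With 5209179 to 7570493 nuclear counts per library and 3 libraries per group, edgeR recovered at most 5.0% of simulated 2-fold increases and DESeq2 at most 17.5% in simulations with 40 genes changed at each fold. Recovery in contrasts where many more genes change was not simulated. The counts of TE genes higher in ddm1 (933 to 1106 over all settings other than single libraries left out, 955 to 1102 with 1 left out) and higher in F1 (583 to 955, and 738 to 872) stayed within 1.5 times the reported counts. The cause of the changes below was not tested. Fits with a library left out or a block have fewer residual degrees of freedom. The filter on low counts was also rerun in each fit, and leaving out a library made its smallest group smaller. Loci with counts in fewer libraries could then pass, so the tested genes could differ. A change in such a fit can therefore not be put down to the library left out alone.

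DESeq2 gave 286 raised and 226 lowered non-TE genes in ddm1 against wild type and 7 lowered TE genes in F1 against wild type. It gave 13 lowered TE genes and 2161 raised non-TE genes in ddm1 against F1, and 27 TE genes above the parental mean. Without a filter on low counts, 694 non-TE genes were lower in ddm1 than in F1, 10 TE genes lay above the parental mean, the location odds ratio in F1 was 1.16 and the Copia and Gypsy odds ratios in ddm1 were 0.848 and 0.754, the Gypsy ratio below 1 with Fisher exact p = 0.00168. With only the 2 groups compared, 565 TE genes were higher in both ddm1 and F1. Without F1 library 3 and ddm1 library 3, raised and lowered non-TE genes numbered 392 and 290 in ddm1 against wild type. In F1 against wild type, raised non-TE genes then numbered 2624 and lowered TE genes 12, and the location odds ratio in F1 was 1.26. That odds ratio was 1.33 under median-ratio scaling and 1.35 with TMM on nuclear non-TE genes, and the Gypsy odds ratio in ddm1 was 1.57 (Fisher exact p = 0.0306) without organelle and rRNA loci. The location odds ratio in ddm1 was 1.42 without a filter and 2.02 with the replicate block. The CACTA odds ratio in ddm1 went from 3.67 without a filter to 40.2 with the stricter filter. Camera with an estimated correlation called 0 of the 16 list results that camera called with a preset one, and fry called 7. The F1 position was 0.236 on TPM. TE shares of nuclear counts were 0.256%, 3.38% and 9.22% in wild type, F1 and ddm1. TE genes detected numbered 106, 704 and 1164 at a TPM of 0.5, and 44, 341.7 and 717 at a TPM of 2.

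With the replicate number as a block, 47 non-TE genes were lower in ddm1 than in wild type, and 2 TE genes lower and 852 non-TE genes higher in F1 than in wild type. With the block, 306 TE genes were higher, 646 non-TE genes higher and 383 lower in ddm1 than in F1, and 7 TE genes lay above the parental mean. The location odds ratio was 1.32 in F1 and the Gypsy odds ratio 0.759 in ddm1. The numbers did not pair the libraries. Deviations from group means correlated at -0.425 to 0.202 in the 9 same-numbered pairs, 2 of them above 0.1. They correlated at -0.257 to 0.439 in the other 18, and 0 libraries correlated best with their own number. The highest values were those of wild-type library 2 with ddm1 library 3 (0.439) and with F1 library 3 (0.341). F1 library 3 and ddm1 library 3 correlated at 0.202. What these libraries share was not tested, and the block does not account for it.

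With each library left out in turn, the ranges in ddm1 against wild type were 3 to 6 lowered TE genes, 123 to 338 raised and 35 to 190 lowered non-TE genes. In F1 against wild type they were 2 to 9 lowered TE genes, 572 to 2190 raised and 874 to 2216 lowered non-TE genes. In ddm1 against F1 they were 252 to 620 raised and 5 to 9 lowered TE genes, 428 to 1803 raised and 254 to 1054 lowered non-TE genes. TE genes below the parental mean ranged from 152 to 426 and those above it from 2 to 29. The F1 position ranged from 0.223 to 0.270, the location odds ratio in F1 from 1.31 to 1.69 and the Gypsy odds ratio in ddm1 from 0.834 to 1.16. In ddm1 the location odds ratio ranged from 2.11 to 2.45, against 3.39 with all libraries, the CACTA odds ratio from 3.27 to 5.18, against 8.11, and the Copia odds ratio from 0.403 to 0.572, against 0.316. Over named genes and all settings, 7505 of 8178 comparisons kept direction and side of the threshold, while 329 lost and 128 gained a call. The direction changed in 216 comparisons of genes not called in the main fit and in 0 of genes called there. No scaling moved the median log2 fold change of all genes by more than 0.067 in size, and the share of higher among called non-TE genes in F1 went from 47.7% to 41.8% at most.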

Other observations

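The tests of parental dose, of scaling on the F1 position and the search for genes seen in wild type alone were chosen after their results were seen, and the other tests before.

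FLC (AT5G10140, chromosome 5, 3173382 to 3179448), a MADS-box repressor of flowering, was the 1 gene with at least 20 counts in each wild-type library (58, 84 and 61) and 0 counts in all 6 F1 and ddm1 libraries, although F1 plants had a Col-0 parent. The level was at least 58.6-fold lower in F1 and at least 58.4-fold lower in ddm1 than in wild type (log2 fold change -8.95 in both, edgeR adjusted p = 0.00215 and 0.00274). No other flowering gene of 11 tested was called in either contrast. The sources used here do not say whether the groups differed in cold treatment or in another background difference, so what these folds reflect stays open.

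The many non-TE genes that differ between F1 and wild type were weighed first. Scaling argued against itself as the cause, since the lowest count over 3 other scalings was 3217 genes against 3356. Dose of the ddm1 parent's chromosomes was argued against too, since 96.2% of the called genes had an F1 mean outside both parental means and 1852 of 3356 (55.2%) were called against both parents in the same direction. On 2 lists of genes not used before, 10 of 14 evening or dark genes, such as GRP7 and DIN10, were higher in F1 and 10 of 17 dawn or light genes, such as LNK2 and GUN4, were lower, and the medians differed by 4.47 on the log2 scale (one-sided permutation p = 4e-05 over genes, which are not independent), with 0 of either list called in ddm1. F1 leaves may thus have been collected at another clock phase or light state than the others, and since all F1 libraries share this and no harvest time is given, an effect of the F1 genotype on the clock stays open and untested.

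The F1 level of TE genes below the parental mean was weighed next. The highest position over 6 scalings or units was 0.262, below the 0.45 that scaling would need. With TE genes chosen on ddm1 libraries 1 and 2 and measured against ddm1 library 3, the position was 0.274, which argues against a bias from choosing genes on high ddm1 counts. The simulation at a true 0.5 returned 0.445 at the lowest, a bias smaller than the gap seen. No table here tells which parental copies were expressed in F1, so what set the level stays open, and a different harvest time and reads shared between copies were not tested for this pattern.

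Non-TE genes raised in ddm1 were weighed last, and 179 nuclear ones could be searched. Of these, 66 (36.9%) matched a TE gene by sequence, against 2.24% of 16590 others. At 95% identity over 50 nt, 13 (7.26%) matched, against 43 (0.259%) of the others. The search covered TE genes only, so diverged or other transposon sequence could be missed and these shares set no upper limit. How much of the pattern transposon sequence in the gene model or shared reads account for therefore cannot be told. Real transcription of these genes cannot be told apart from either, because the reads were not analysed here. Among the 113 that matched no TE gene, 28 (24.8%) had a TE gene within 2 kb, against 3.50% of 16219 others (Fisher exact p = 4.2e-16). Transcription from a neighbouring TE gene is thus a candidate explanation for those. Genes in TE-rich regions would have such neighbours whatever the cause, and the others were not matched for region. Neither strand nor the neighbour's own change was checked, so the test cannot decide between these.

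Splitting the 6 libraries of each comparison in all 10 ways gave too few splits for a share under 0.05, and in each case 1 split, the real one, reached the real count. For comparisons between groups, the splits filtered and fitted only the 6 libraries, so the real counts differ from those with all 9 libraries. The real splits called 1053 TE and 252 non-TE genes for ddm1 against wild type, 587 and 3189 for F1 against wild type, 565 and 1906 for ddm1 against F1, and 327 TE genes for F1 against the parental mean, with 0 as the highest count of the other splits in each.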
